A study of Mus musculus with 12 samples.

How the data were processed

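Gene expression was measured with Affymetrix mouse arrays that carry 45101 probe sets. The 12 arrays came from 4 kinds of culture, with 3 arrays of each, and the series record speaks of independent experiments for each condition. The cells were mouse bone marrow, taken after treatment of the mice with 5-fluorouracil, infected with a retrovirus for the NUP98-HOXD13 fusion gene and kept in liquid culture for 4 weeks. The medium held human IL-6 at 10 ng/ml, mouse IL-3 at 6 ng/ml and mouse stem cell factor at 100 ng/ml. A second retrovirus was then introduced by 2 days of growth on irradiated E86 cells, a fibroblast line that releases the virus. RNA was taken from sorted cells. The gate of the sort and the time between infection and RNA extraction are not given in the sources used here.

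The values deposited by the authors are array intensity, as the signal of each probe set from the software GCOS 1.2 on a linear scale. On every array the mean signal without the lowest and highest 2% of values was 100, as computed from the values themselves, so each array had been scaled to a common target. The background and summary settings are not given in the sources used here. No detection call was used here.

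The signal of each probe set was turned into log2(signal + 16), and the authors' scaling was kept. Adding 16 makes the log2 differences of dim genes smaller than the ratios of their signals. From the 45101 probe sets, 64 array-control probe sets were left out. Of the rest, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. The symbols were looked up through 34741 Entrez gene IDs, and 0 changed. A probe set was kept when it lay above the 40th percentile of its array on at least 3 of the 12 arrays, which left 31726. For each gene the kept probe set with the highest mean was used, which mattered for 6532 genes with more than 1. The 19990 features tested were 14005 genes with a symbol and 5985 probe sets without a single symbol. The word gene stands for such a feature in the counts below.

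One linear model with the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), which leaves 8 residual degrees of freedom. The replicate numbers were not used as a block. The 6 comparisons set each construct against the control vector and the constructs against each other. P-values were two-sided and adjusted by Benjamini and Hochberg within a comparison, and a gene passed at an adjusted p below 0.05. Log2 differences are given with the standard error (SE) from the model, and signals as mean ± SD of 3 arrays. A rank-based exact test of 3 arrays against 3 cannot give a two-sided p below 0.1, so the tests rest on the shared spread of the model. The number of arrays limits the precision.

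The comparisons, the filter, the named-gene rule, 28 gene lists and the alternatives were chosen before the data were examined, except where stated. The lists hold 492 members, of which 451 matched a gene on the array and 15 stand in more than 1 list. The 26 lists with at least 5 measured members were tested. They cover genes linked to Meis1, the Hoxa cluster and its partners, stem and progenitor cells, primary and secondary granules, monocytes and macrophages, mast cells and basophils, erythroid cells, megakaryocytes, B cells, T and NK cells, dendritic cells, fibroblasts, G1/S and G2/M, D cyclins, chemokines, immediate early genes, interferon, NF-kB, cholesterol synthesis, hypoxia, ATF4 stress, p53, Polycomb complexes and heat shock. The eosinophil list had 3 measured members and the sex chromosome list 1, so neither was tested. Lists were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Unless stated otherwise, a list p-value is from the preset correlation, and it can be far smaller than the one from the estimated correlation. At the preset correlation some mixed splits of the arrays gave nearly as many lists as the real groups, or more, as described below. A pass at the preset correlation alone is therefore weak evidence. List p-values were adjusted over the 26 lists within a comparison. Members that passed were counted over all genes and adjusted over the list alone.

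The named genes were chosen by rule. Against control they were the 10 higher and 10 lower genes with the largest log2 difference among those that passed, carried 1 symbol and had all 3 arrays of one group beyond all 3 of the other. Between constructs they were the 5 higher and 5 lower. Added to these were Meis1, Cbx2, Trib2, Ccl3 and Flt3, up to 4 members with the largest log2 difference of each list that passed (or the 2 with the smallest p where no member passed), and 5 genes per direction for each overlap. The text names a part of them.

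Because comparisons share arrays, each overlap of calls was set beside the number expected from independent lists and beside 100 simulations of unchanged groups. The tests were tried on simulated data with the means and spreads of the real features. With 200 changed features, a log2 change of 2 was recovered in 100% of cases in every comparison. A log2 change of 1 was recovered in 79.1% of cases for MEIS1-WT against control and against MEIS1-deltaHD, and in 92.5% for M33-MEIS1 against MEIS1-WT. A log2 change of 0.5 was recovered in 34.3% to 50.7% of cases, so many changes of that size are missed where few genes differ. Against control 6138 to 7309 genes passed, which makes the adjusted threshold less strict than with 200 changed features. The recovered shares therefore do not measure what is missed in the comparisons with control. The share of calls that were false lay between 3.36% and 6.88%. A list shifted by 0.5 was called in 20 of 20 draws, and 2 unshifted lists were called over all draws. The simulated genes were drawn independently of each other. In the real data the correlation between list members was estimated at 0.32 for the monocyte list and 0.742 for the G2/M list. These draws therefore do not measure how often lists are falsely called in the real data.

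Alternatives changed 1 choice at a time: an added constant of 1 or 64, no filter or a stricter one, quantile normalization, median scaling of each array, no intensity trend, array weights, the 2 compared groups alone, a replicate block, all probe sets tested singly, probe sets that may match several transcripts or genes (suffixes x, s and a) left out, a required log2 difference of 1, an estimated correlation for the lists, and each array left out in turn. The list tests under median scaling were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.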

Results

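Expression was compared between 4 kinds of mouse bone marrow culture, all transformed by NUP98-HOXD13, a leukaemia fusion gene that joins a nucleoporin to a homeobox protein. Control cultures carried the vector MIY, which encodes yellow fluorescent protein. The others carried full-length MEIS1 (MEIS1-WT), MEIS1 without its DNA-binding homeodomain (MEIS1-deltaHD), or M33-MEIS1. M33 is an older name of Cbx2, a Polycomb protein of repressive chromatin, and the labels say no more about this construct. From its name alone it is taken here as MEIS1 joined to M33. Each group had 3 arrays, and the median signal of an array lay between 13.1 and 21.6. It was 19.2 ± 2.19 (SD, n = 3) in control, 14.8 ± 0.519 with MEIS1-WT, 13.4 ± 0.409 with MEIS1-deltaHD and 14.9 ± 1.03 with M33-MEIS1. Arrays of the same group correlated at 0.982 to 0.989 across genes, which are not independent replicates. Some construct arrays were as close to another group. Replicate 2 of M33-MEIS1 correlated at 0.9887 with an array of another group and at 0.9836 with 1 array of its own.

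The control cultures stood far from all 3 constructs, and MEIS1-WT stood apart from the other constructs. The first principal component held 46.9% of the variance and put the control arrays at -48.8, -59.8 and -48.1, with every construct array between 5.96 and 24.5. The second held 12.7% and put the MEIS1-WT arrays between 22.2 and 26.5, while MEIS1-deltaHD and M33-MEIS1 arrays lay below 0. The third held 6.77% and set replicate 3 of M33-MEIS1 apart, at -34.7. Measures of RNA and labelling also differed between control and the constructs, not all in 1 direction. The 3' to 5' signal ratio of actin was highest in control, at 1.5 ± 0.00980 in control against 1.46 ± 0.0200, 1.35 ± 0.0523 and 1.38 ± 0.0676 with MEIS1-WT, MEIS1-deltaHD and M33-MEIS1. The same ratio of Gapdh was lowest in control, at 0.783 ± 0.0153 against 0.832 ± 0.00835, 0.819 ± 0.00847 and 0.850 ± 0.0281. The mean log2 signal of the spiked control transcripts was 10.5 ± 0.130 in control and 10.1 ± 0.216, 10.0 ± 0.188 and 10.2 ± 0.161 in the same order.

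**Figure D1:**
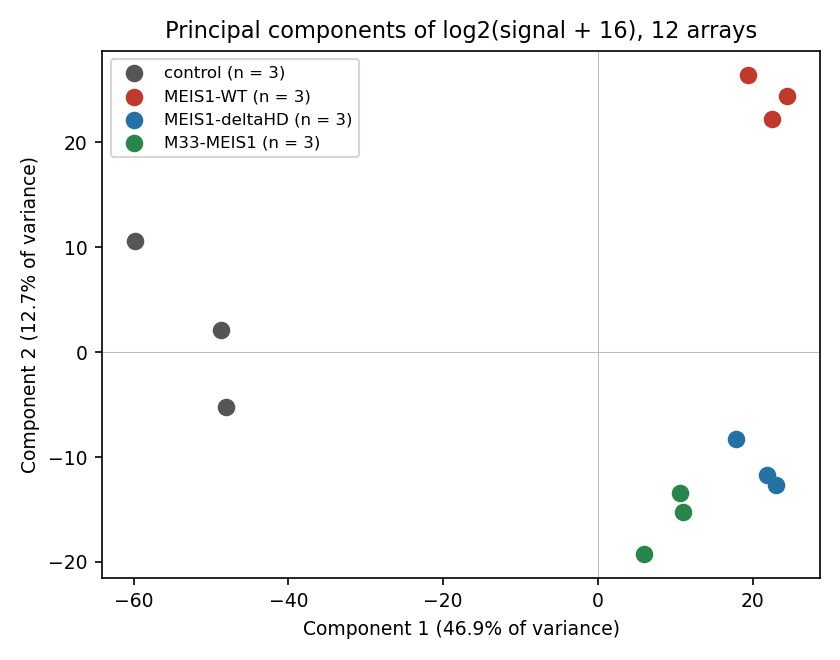
Principal components 1 and 2 of the log2 values, with 1 point per array coloured by group and the share of variance on each axis. The control arrays lie between -59.8 and -48.1 on the first component, and the MEIS1-WT arrays between 22.2 and 26.5 on the second.

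The mouse Meis1 probe set was lower, not higher, with the constructs. Its signal was 187 ± 18.4 in control, 141 ± 10.4 with MEIS1-WT, 110 ± 9.96 with MEIS1-deltaHD and 117 ± 14.6 with M33-MEIS1. It passed against control with MEIS1-deltaHD (log2 difference -0.69 ± 0.113 SE, adjusted p = 3.03e-05) and with M33-MEIS1 (-0.62 ± 0.113, adjusted p = 1.52e-04). With MEIS1-WT the difference of -0.37 (adjusted p = 0.0128) no longer passed without control replicate 1 (-0.31, adjusted p = 0.074), without MEIS1-WT replicate 1 (-0.32, adjusted p = 0.0644) or after median scaling (-0.18, adjusted p = 0.314). With all kept probe sets tested singly, 1 of 2 further Meis1 probe sets passed as lower with all 3 constructs, and the other, at 18.4 in control, passed with none (adjusted p = 0.584, 0.518 and 0.971). The sequence of the constructs is not given in the sources used here, so it is open whether these probe sets see the inserted genes. The Cbx2 probe set used in the comparisons did not pass in any of the 6, with log2 differences from control of -0.26 (adjusted p = 0.235), -0.41 (adjusted p = 0.0521) and -0.28 (adjusted p = 0.199). A second Cbx2 probe set read 51.3 ± 9.60 with M33-MEIS1 and 7.12 ± 5.47, 10.2 ± 4.89 and 11.4 ± 2.38 in control, MEIS1-WT and MEIS1-deltaHD. Tested singly with limma and without the filter, it was higher with M33-MEIS1 than in control (log2 difference 1.56, adjusted p = 5.85e-05). It was also higher than with MEIS1-deltaHD (1.29, adjusted p = 0.0188) and MEIS1-WT (1.37, adjusted p = 9.73e-04). Hoxd13 was dim in every group, at 11.1 ± 4.51 in control.

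Against the control vector, cells with MEIS1-WT had much lower levels of monocyte, macrophage and interferon-response genes, and higher levels of genes for DNA replication, cholesterol synthesis and a set of genes linked to Meis1. The comparison asks what full-length MEIS1 adds to NUP98-HOXD13 cells. Lysozyme (Lyz2) fell from 5391 ± 119 to 112 ± 13 (log2 difference -5.41 ± 0.0814, adjusted p = 9.02e-24). The macrophage colony-stimulating factor receptor Csf1r fell from 1590 ± 101 to 32.3 ± 5.86 (-5.06 ± 0.0914, adjusted p = 2.9e-22). Dlk1, an imprinted membrane protein related to Notch ligands, rose from 260 ± 40.7 to 1633 ± 183 (2.59 ± 0.106, adjusted p = 1.72e-15).

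Of the other genes highest with MEIS1-WT relative to control, Slc35d3, a transporter needed for platelet dense granules, differed by 2.75 and Ddx4, an RNA helicase best known from germ cells, by 2.40 on the log2 scale. The fatty acid desaturase Scd1 differed by 2.33, the transferrin receptor Tfrc by 1.95 and thymidine kinase Tk1 by 1.84. Among the lowest were Tgfbi, a secreted matrix protein (-5.77), Slfn4 (-5.61), Ms4a6d (-5.40), the macrophage pore-forming protein Mpeg1 (-5.27), cathepsin S (Ctss, -5.12) and Gpnmb (-5.07). In the list of monocyte and macrophage genes, 19 of 20 were lower and 0 higher (0 higher and 20 lower adjusted over the list alone). The list median was -2.47 (adjusted p = 3.37e-28, adjusted p = 0.0108 with an estimated correlation). All 17 interferon-response genes were lower over all genes and adjusted over the list alone. Their median was -3.50 (adjusted p = 1.09e-25, adjusted p = 0.0145 with an estimated correlation). They included the antiviral genes Rsad2 (-4.70) and Oasl2 (-4.66) and the interferon feedback protease Usp18 (-4.98). Of 15 secondary granule genes of neutrophils, 7 were lower and 0 higher by both counts (median -0.35, adjusted p = 3.7e-05), among them the oxidase subunit Cybb (-4.93) and the collagenase Mmp8 (-4.28). The list of primary granule and early myeloid genes had 8 of 14 lower and 1 higher by both counts, with a median of -0.25 (adjusted p = 0.0189, adjusted p = 0.192 with an estimated correlation). The receptor Csf3r (-1.38) and the transcription factor Gfi1 (-1.01) were lower, while Elane differed by 0.13 (adjusted p = 0.63). That list did not pass without control replicate 3 (adjusted p = 0.0823) or after median scaling (adjusted p = 0.0702).

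All 15 genes of cholesterol synthesis were higher with MEIS1-WT than in control by both counts (median 1.43, adjusted p = 6.24e-22, adjusted p = 0.0113 with an estimated correlation). Examples were Cyp51 (1.88), Dhcr7 (1.84) and Lss (1.64). Of 19 G1/S genes, 18 were higher and 0 lower by both counts (median 0.89, adjusted p = 2.78e-20, adjusted p = 0.0297 with an estimated correlation). They included cyclin E1 (Ccne1, 1.56), the replication licensing factor Cdc6 (1.52) and ribonucleotide reductase Rrm1 (1.45). Heat shock genes were higher in 10 of 14 and lower in 0 by both counts (median 0.45, adjusted p = 1.12e-07), led by Hsph1 (1.53). Targets of ATF4 and amino acid stress were lower in 14 of 18 and higher in 1 (1 higher and 15 lower adjusted over the list alone, median -0.69, adjusted p = 2.87e-09), with Trib3 at -3.04 and Atf5 at -2.74. Of 14 genes tied to Meis1 in earlier leukaemia work, 11 were higher and 0 lower (11 and 1 adjusted over the list alone, median 1.00, adjusted p = 4.98e-09). Trib2 and Ccl3 stand in the title of the series, so this list is not independent evidence. The chemokine Ccl3 rose from 1667 ± 180 to 3431 ± 191 (1.04 ± 0.114, adjusted p = 1.02e-07), and the receptor tyrosine kinase Flt3 from 158 ± 18.6 to 331 ± 35.5 (1.00 ± 0.126, adjusted p = 8.4e-07). The pseudokinase Trib2 rose from 19.2 ± 9.39 to 61.6 ± 12.3 (1.16 ± 0.207, adjusted p = 8.99e-05). With the probe sets shared between transcripts or genes left out, Trib2 differed by 0.18 (adjusted p = 0.591), where the remaining probe set read 8.33 in control and 11.2 with MEIS1-WT.

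Mast cell genes were lower in 9 of 13 and higher in 1 with MEIS1-WT relative to control (1 higher and 10 lower adjusted over the list alone, median -0.65, adjusted p = 2.65e-04), with granzyme B (Gzmb) at -2.08 and the IgE receptor chain Fcer1a at -1.61. This list gave adjusted p = 0.192 with an estimated correlation. G2/M genes were higher in 11 of 19 and lower in 0 (12 and 0 adjusted over the list alone, median 0.33, adjusted p = 8.4e-07), and adjusted p = 0.356 with an estimated correlation. Hypoxia and glycolysis genes were higher in 9 of 17 and lower in 3 by both counts (median 0.26, adjusted p = 3.7e-05, adjusted p = 0.266 with an estimated correlation), with the prolyl hydroxylase Egln3 at 1.69. Chemokines and cytokines were lower in 11 of 21 and higher in 2 by both counts (median -0.72, adjusted p = 0.0189), with Ccl6 at -3.94 and Ccl2 at -2.59. The chemokine list gave adjusted p = 0.0555 without control replicate 2 and adjusted p = 0.462 with an estimated correlation. Of the 13 lists that passed, 8 also passed with an estimated correlation. Those 8 then had adjusted p between 0.0108 and 0.0297, each larger than at the preset correlation. In all, 6545 of 19990 genes passed, 2665 higher and 3880 lower, and 931 of them differed by at least 1 on the log2 scale. The direction of the small differences depends on scaling: the median of all genes was -0.124 here and shifted by 0.127 after quantile normalization and 0.190 after median scaling, which moved the share of calls that were higher from 40.7% to 51.1% and 67.5%.

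MEIS1-deltaHD differed from control in most of the same gene groups. Monocyte and interferon genes were lower, cholesterol and G1/S genes were higher, and the list of genes linked to Meis1 did not pass. The comparison asks what remains of the effect when the homeodomain is missing. The interferon-induced gene Rtp4 fell from 1534 ± 204 to 15.4 ± 4.09 (log2 difference -5.63 ± 0.151, adjusted p = 2.8e-18). P2rx3, an ATP-gated channel, fell from 1174 ± 172 to 46.3 ± 5.07 (-4.25 ± 0.123, adjusted p = 1.16e-17). Neutrophil elastase (Elane) rose from 740 ± 311 to 2174 ± 209 (1.63 ± 0.179, adjusted p = 1.09e-07), and Ms4a3, a gene of granulocyte progenitors, from 1073 ± 346 to 3866 ± 284 (1.88 ± 0.134, adjusted p = 7.85e-11). The primary granule list, with 4 of 14 higher and 3 lower by both counts, did not pass (adjusted p = 0.144), nor did the secondary granule list, with 4 of 15 higher and 4 lower by both counts (adjusted p = 0.902).

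Other genes highest with MEIS1-deltaHD relative to control were Tfrc (1.95), the endoplasmic reticulum protein Sdf2l1 (1.94), the flap endonuclease Fen1 (1.89), Tk1 (1.71), Scd1 (1.70), Ccne1 (1.57) and the tubulin Tubb6 (1.55). The lowest included Slfn4 (-5.42), Ifit1bl1 (-5.13), Usp18 (-5.13), Rsad2 (-5.02), Oasl2 (-4.69), Ms4a4c (-4.51) and Gpnmb (-4.27). All 17 interferon genes were lower by both counts (median -3.24, adjusted p = 2.68e-23). Of 20 monocyte genes 17 were lower and 0 higher (0 and 18 adjusted over the list alone, median -1.90, adjusted p = 1.91e-16), with Ctss at -3.26 and Lyz2 at -3.07. All 15 cholesterol genes were higher by both counts (median 1.19, adjusted p = 3.73e-19), and so were all 19 G1/S genes (median 0.87, adjusted p = 8.11e-20). All 18 ATF4 targets were lower by both counts (median -0.95, adjusted p = 2.76e-12), including Trib3 (-3.48), Atf5 (-2.99) and the stress factor Ddit3 (-1.73). Heat shock genes were higher in 9 of 14 and lower in 0 (10 and 0 adjusted over the list alone, median 0.43, adjusted p = 2.26e-07), with Hsph1 at 1.54. Of the 14 genes linked to Meis1, 2 were higher and 8 lower (2 and 9 adjusted over the list alone), and the list did not pass (median -0.39, adjusted p = 0.3). Ccl3 differed by 0.20 (adjusted p = 0.179) and Trib2 by -0.28 (adjusted p = 0.319). Flt3 was at -0.39 (adjusted p = 0.0182), a call lost without control replicate 1 (adjusted p = 0.0738), control replicate 2 (adjusted p = 0.0615) or MEIS1-deltaHD replicate 3 (adjusted p = 0.116), and after quantile normalization (adjusted p = 0.0877) or median scaling (adjusted p = 0.505).

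A further 6 lists passed for MEIS1-deltaHD against control at the preset correlation and not at the estimated one. Immediate early genes were lower in 10 of 21 and higher in 0 by both counts (median -0.39, adjusted p = 0.0103, adjusted p = 0.375 with an estimated correlation), with Fos at -2.58 and Egr1 at -1.48. NF-kB targets were lower in 11 of 16 and higher in 0 (1 higher and 11 lower adjusted over the list alone, median -0.73, adjusted p = 4.96e-03, adjusted p = 0.258 with an estimated correlation), with Il1b at -1.87. Megakaryocyte genes were lower in 10 of 16 and higher in 0 (0 and 12 adjusted over the list alone, median -0.66, adjusted p = 1.34e-03, adjusted p = 0.232 with an estimated correlation), such as P-selectin (Selp, -1.08). Chemokines and cytokines were lower in 12 of 21 and higher in 0 (1 higher and 12 lower adjusted over the list alone, median -0.49, adjusted p = 1.82e-03, adjusted p = 0.336 with an estimated correlation). G2/M genes were higher in 14 of 19 and lower in 0 by both counts (median 0.45, adjusted p = 1.96e-09, adjusted p = 0.322 with an estimated correlation). Hypoxia genes were higher in 7 of 17 and lower in 3 (8 and 4 adjusted over the list alone, median 0.15, adjusted p = 5.49e-03, adjusted p = 0.416 with an estimated correlation), with Egln3 at 1.49 and the angiogenic factor Vegfa at -1.33. The other 6 lists also passed with an estimated correlation, among them the monocyte and G1/S lists at adjusted p = 0.0405 each. In all, 7309 genes passed, 2764 higher and 4545 lower, of which 928 differed by at least 1. The median of all genes was -0.170 and shifted by 0.156 and 0.255 under quantile normalization and median scaling, where 49.7% and 70.8% of calls were higher in place of 37.8%.

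M33-MEIS1 also had lower interferon genes and higher cholesterol and G1/S genes than control, and lower monocyte genes, a list that passed at the preset correlation only. Some mast cell and neutrophil genes were higher and others lower. The comparison asks how the form joined to M33 differs from the empty vector. The Mycn probe set used in the comparisons, for a transcription factor of the Myc family, fell from 6748 ± 424 to 1724 ± 135 (log2 difference -1.96 ± 0.081, adjusted p = 8.69e-15). With all kept probe sets tested singly, the other 2 Mycn probe sets, at 413 and 69.8 in control, differed by -0.42 (adjusted p = 0.0433, and 0.0926 without the filter) and -0.31 (adjusted p = 0.198). The calcium-binding neutrophil protein S100a9 rose from 341 ± 83.0 to 1044 ± 102 (1.60 ± 0.130, adjusted p = 1.14e-09) and Ngp, a neutrophil granule protein, from 61.7 ± 11.3 to 240 ± 35.3 (1.72 ± 0.142, adjusted p = 1.32e-09). Other secondary granule genes fell, such as Mmp8 (-1.95), Cybb (-1.88) and Lcn2 (-1.61), and the list of 15, with 4 higher and 3 lower (5 and 3 adjusted over the list alone), did not pass (adjusted p = 0.334). The protease Mcpt8, of the list of mast cell and basophil genes, rose from 375 to 903 (1.23, adjusted p = 2.4e-11).

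Other genes highest with M33-MEIS1 relative to control were Scd1 (2.02), Tfrc (2.02), Ms4a3 (1.80), Fen1 (1.72), Tk1 (1.69) and the sterol enzymes Hsd17b7 (1.67) and Nsdhl (1.61). The lowest were mostly interferon genes: Rtp4 (-4.85), Slfn4 (-4.73), Usp18 (-4.52), Rsad2 (-4.46), Oasl2 (-4.42), Ifit1 (-3.76) and Parp12 (-3.62), together with P2rx3 (-4.09) and Gpnmb (-3.70). All 17 interferon genes were lower by both counts (median -3.15, adjusted p = 3.02e-27), all 15 cholesterol genes were higher by both counts (median 1.25, adjusted p = 7.88e-23), and 18 of 19 G1/S genes were higher and 0 lower by both counts (median 0.80, adjusted p = 2.77e-22). ATF4 targets were lower in 17 of 18 and higher in 0 (0 and 18 adjusted over the list alone, median -0.89, adjusted p = 2.08e-14), and heat shock genes higher in 10 of 14 and lower in 0 by both counts (median 0.41, adjusted p = 5.96e-08). Monocyte genes were lower in 17 of 20 and higher in 0 (0 and 18 adjusted over the list alone, median -1.25, adjusted p = 3.92e-14), with Ctss at -2.22 and Lyz2 at -1.99, and adjusted p = 0.0555 with an estimated correlation. Mast cell genes were higher in 6 of 13 and lower in 2 by both counts (median 0.33, adjusted p = 1.09e-03, adjusted p = 0.224 with an estimated correlation). The proteases Mcpt2 (1.58) and Tpsab1 (0.89) and the histamine-forming enzyme Hdc (0.97) were higher. Stem and progenitor genes were lower in 12 of 20 and higher in 1 by both counts (median -0.45, adjusted p = 9.14e-04, adjusted p = 0.132 with an estimated correlation), among them Hlf (-1.26), Eya1 (-0.92) and Flt3 (-0.80).

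Immediate early genes were lower in 13 of 21 and higher in 0 with M33-MEIS1 relative to control (0 and 14 adjusted over the list alone, median -0.50, adjusted p = 1.1e-05, adjusted p = 0.189 with an estimated correlation), with Fos at -2.91 and Egr1 at -2.01. NF-kB targets were lower in 8 of 16 and higher in 0 (0 and 10 adjusted over the list alone, median -0.50, adjusted p = 4.46e-03, adjusted p = 0.224 with an estimated correlation). Chemokines were lower in 8 of 21 and higher in 0 by both counts (median -0.26, adjusted p = 0.0254, adjusted p = 0.413 with an estimated correlation), a call lost without control replicate 2 (adjusted p = 0.101). G2/M genes were higher in 13 of 19 and lower in 0 (14 and 0 adjusted over the list alone, median 0.56, adjusted p = 7.47e-11, adjusted p = 0.224 with an estimated correlation). Hypoxia genes were higher in 10 of 17 and lower in 3 (11 and 3 adjusted over the list alone, median 0.26, adjusted p = 1.37e-05, adjusted p = 0.224 with an estimated correlation). Of the genes linked to Meis1, 3 were higher and 6 lower (3 and 7 adjusted over the list alone), and the list did not pass (median -0.28, adjusted p = 0.359). Trib2 differed by -0.36 (adjusted p = 0.208) and Ccl3 by 0.08 (adjusted p = 0.658). Of the 13 lists that passed, 5 also passed with an estimated correlation. In all, 6138 genes passed, 2473 higher and 3665 lower, of which 634 differed by at least 1. The median of all genes was -0.127 and shifted by 0.118 and 0.186 under quantile normalization and median scaling, where 50.7% and 70.0% of calls were higher in place of 40.3%.

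**Figure D2:**
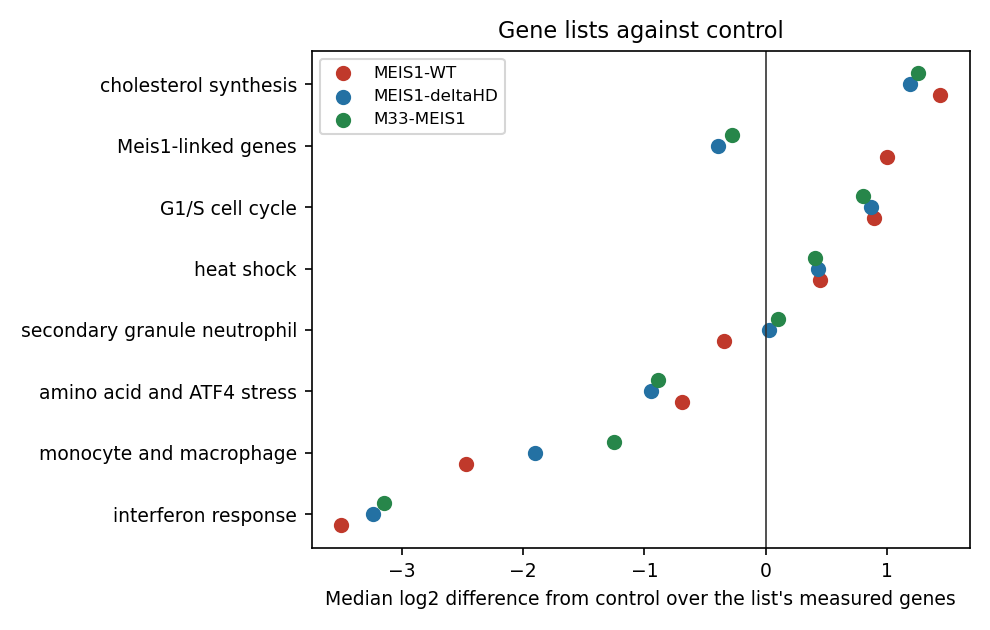
Median log2 difference from control (x axis) of the 8 gene lists that passed with an estimated correlation in at least 1 construct, with 1 point per construct. The interferon list lies at -3.50, -3.24 and -3.15 and the cholesterol list at 1.43, 1.19 and 1.25, while the Meis1-linked list lies at 1.00, -0.39 and -0.28.

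Cells with MEIS1-WT had higher levels of genes linked to Meis1 and lower levels of monocyte and granulocyte genes than cells with MEIS1-deltaHD. This comparison asks which changes need the homeodomain, between constructs that both lie far from control. Dlk1 was 1633 ± 183 with MEIS1-WT and 109 ± 7.11 with MEIS1-deltaHD (log2 difference 3.72 ± 0.106, adjusted p = 1.23e-17). Csf1r was 32.3 ± 5.86 against 425 ± 23.8 (-3.20 ± 0.0914, adjusted p = 1.23e-17). Trib2 was 61.6 ± 12.3 against 12.7 ± 4.76 (1.44 ± 0.207, adjusted p = 4.44e-05), and Ccl3 was 3431 ± 191 against 1948 ± 481 (0.84 ± 0.114, adjusted p = 2.13e-05). Trib2 differed by 0.19 (adjusted p = 0.78) with shared probe sets left out.

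Further genes higher with MEIS1-WT than with MEIS1-deltaHD were Ddx4 (2.99), Slc35d3 (2.86), the G-protein regulator Rgs1 (2.38) and P2rx3 (2.22). Further lower genes were Ifitm6 (-2.68), Cybb (-2.62), Igsf6 (-2.47) and Mpeg1 (-2.47). Monocyte genes were lower in 14 of 20 and higher in 0 (0 and 15 adjusted over the list alone, median -1.22, adjusted p = 3.12e-43), including Lyz2 (-2.34) and the clotting factor chain F13a1 (-2.17). Secondary granule genes were lower in 9 of 15 and higher in 0 by both counts (median -0.68, adjusted p = 1.27e-18), including S100a9 (-2.36), S100a8 (-2.01) and Ngp (-1.89). Primary granule genes were lower in 10 of 14 and higher in 0 (0 and 12 adjusted over the list alone, median -0.51, adjusted p = 2.07e-17), including Elane (-1.50) and Ms4a3 (-1.22). Of the 14 genes linked to Meis1, 10 were higher and 0 lower by both counts (median 1.14, adjusted p = 1.74e-23), among them Hlf (1.94), platelet factor 4 (Pf4, 1.77), Flt3 (1.38) and Ccl4 (1.58). This list holds Trib2 and Ccl3 of the series title and is not independent evidence. These 4 lists also passed with an estimated correlation.

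**Figure D3:**
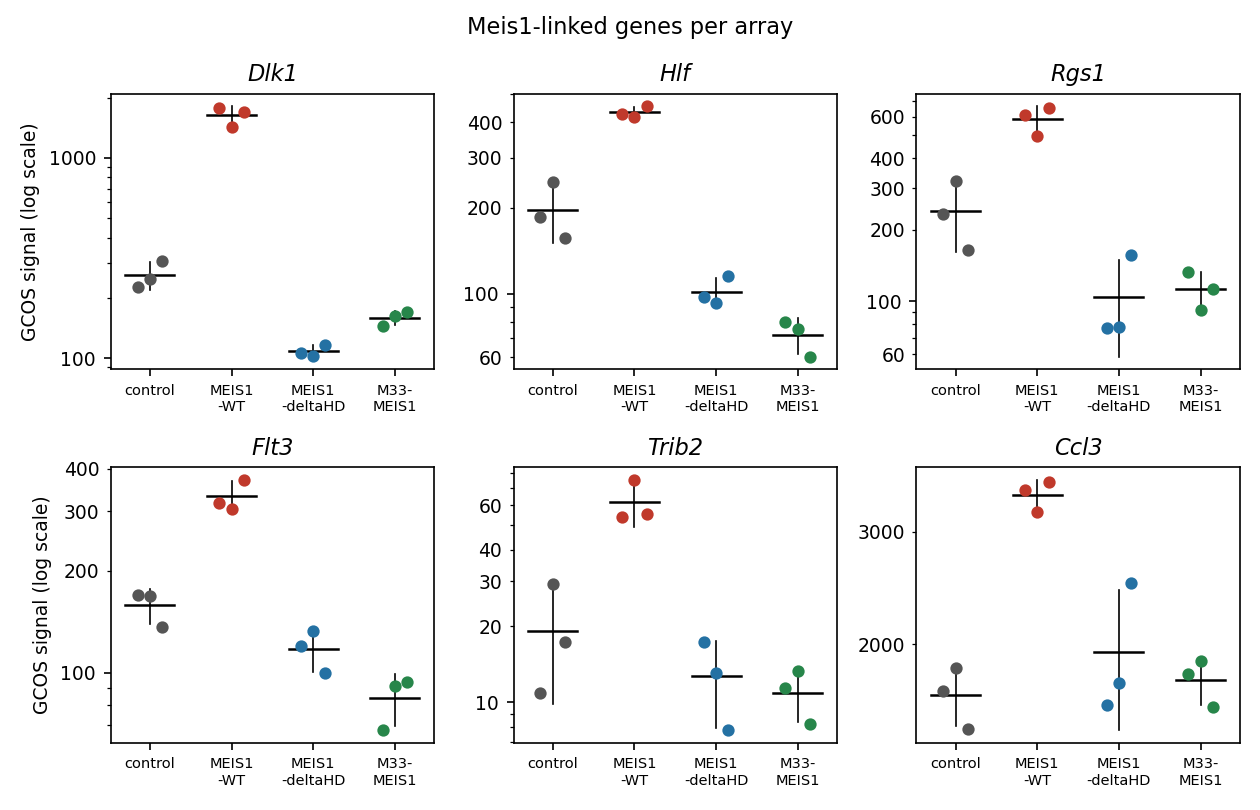
GCOS signal per array on a log axis for genes linked to Meis1, with 1 point per array, a line at the mean and bars of 1 SD (n = 3). Dlk1 has a mean of 1633 with MEIS1-WT, 260 in control, 109 with MEIS1-deltaHD and 159 with M33-MEIS1.

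Other lists passed for MEIS1-WT against MEIS1-deltaHD at the preset correlation and not at the estimated one. Immediate early genes were higher in 6 of 21 and lower in 0 (14 and 1 adjusted over the list alone, median 0.38, adjusted p = 2.98e-07, adjusted p = 0.141 with an estimated correlation), with the zinc finger factors Egr3 (1.24) and Egr1 (1.19). Megakaryocyte genes were higher in 5 of 16 and lower in 1 (9 and 1 adjusted over the list alone, median 0.52, adjusted p = 1.12e-05, adjusted p = 0.11 with an estimated correlation), with the platelet chemokine Ppbp at 1.37, integrin Itgb3 at 0.98 and thrombospondin Thbs1 at -1.19. Stem and progenitor genes were higher in 7 of 20 and lower in 3 (9 and 3 adjusted over the list alone, median 0.15, adjusted p = 1.78e-03, adjusted p = 0.161 with an estimated correlation), with Angpt1 at 0.83 and Prom1 at -0.95. Cholesterol genes were higher in 6 of 15 and lower in 0 (9 and 0 adjusted over the list alone, median 0.31, adjusted p = 1.56e-06, adjusted p = 0.168 with an estimated correlation), with Cyp51 at 0.58. NF-kB targets were higher in 5 of 16 and lower in 1 by both counts (median 0.16, adjusted p = 5.25e-03, adjusted p = 0.204 with an estimated correlation), with Cxcl2 at 1.61. Mast cell genes were lower in 4 of 13 and higher in 0 by both counts (median -0.19, adjusted p = 1.32e-03, adjusted p = 0.204 with an estimated correlation), with Mcpt2 at -1.08. Hypoxia genes were higher in 3 of 17 and lower in 0 (median 0.15, adjusted p = 1.74e-04, adjusted p = 0.248 with an estimated correlation).

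ATF4 targets were higher in 4 of 18 and lower in 1 with MEIS1-WT relative to MEIS1-deltaHD (6 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.0118, adjusted p = 0.204 with an estimated correlation), with the mTOR inhibitor Ddit4 at 0.94 and Cebpb at -0.69, and the list did not pass without MEIS1-deltaHD replicate 2 (adjusted p = 0.0757). The p53 targets were higher in 3 of 16 and lower in 0 by both counts (median 0.15, adjusted p = 0.0141, adjusted p = 0.241 with an estimated correlation), with the pro-apoptotic gene Bbc3 at 0.65. That list did not pass without MEIS1-deltaHD replicate 2 (adjusted p = 0.0755) or MEIS1-WT replicate 3 (adjusted p = 0.0687). In the G2/M list, 0 of 19 genes passed with limma over all genes or adjusted over the list alone, and 3 were lower at an unadjusted p below 0.05, with a median of -0.10 (adjusted p = 0.0118, adjusted p = 0.654 with an estimated correlation). In all, 1050 genes passed, 485 higher and 565 lower, of which 169 differed by at least 1. After median scaling 297 were higher and 660 lower. Without MEIS1-deltaHD replicate 1 the count was 692, and without an intensity trend it was 605, where Cxcl2 (adjusted p = 0.0583) and Egr3 (adjusted p = 0.057) did not pass.

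M33-MEIS1 and MEIS1-deltaHD were the closest pair by number of genes, and mast cell and monocyte genes were higher with M33-MEIS1. The comparison asks what the form joined to M33 does beyond MEIS1 without a homeodomain. Granzyme B (Gzmb), found in granules of mast cells and cytotoxic cells, was 999 ± 139 with M33-MEIS1 and 258 ± 79.4 with MEIS1-deltaHD (log2 difference 1.92 ± 0.169, adjusted p = 1.62e-07). The Mycn probe set used in the comparisons was 1724 ± 135 against 6449 ± 428 (-1.90 ± 0.081, adjusted p = 7.43e-14), while the other 2, with all kept probe sets tested singly, differed by -0.12 (adjusted p = 0.845) and 0.085 (adjusted p = 0.915). The chemokine Ccl6 was 490 ± 91.0 against 146 ± 1.44 (1.63 ± 0.114, adjusted p = 2.61e-09).

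Of 13 mast cell genes, 9 were higher and 0 lower with M33-MEIS1 than with MEIS1-deltaHD (13 and 0 adjusted over the list alone, median 0.87, adjusted p = 1.58e-32). They included the chymase Cma1 (1.65) and the tryptases Tpsab1 (1.47) and Tpsb2 (1.33), and Tpsb2 was at -0.039 with shared probe sets left out. Monocyte genes were higher in 7 of 20 and lower in 0 (15 and 0 adjusted over the list alone, median 0.54, adjusted p = 7.69e-21), including Lyz2 (1.07), Ctss (1.05), Ms4a6d (1.01) and F13a1 (0.89). Secondary granule genes were higher in 1 of 15, Mmp8 (1.06), and lower in 0 (5 and 0 adjusted over the list alone, median 0.34, adjusted p = 3.46e-05). These 3 lists also passed with an estimated correlation. Megakaryocyte genes were higher in 3 of 16 and lower in 0 (6 and 0 adjusted over the list alone, median 0.38, adjusted p = 3.24e-07, adjusted p = 0.0633 with an estimated correlation), with Pf4 at 1.03. Immediate early genes were lower in 2 of 21 and higher in 0 (0 and 5 adjusted over the list alone, median -0.13, adjusted p = 1.53e-04, adjusted p = 0.315 with an estimated correlation). Those 2 were Jun (-0.66, adjusted p = 0.0272) and Dusp5 (-0.69, adjusted p = 0.0325). Jun did not pass without M33-MEIS1 replicate 1 (adjusted p = 0.156), M33-MEIS1 replicate 3 (adjusted p = 0.154), MEIS1-deltaHD replicate 1 (adjusted p = 0.162) or MEIS1-deltaHD replicate 3 (adjusted p = 0.138). Dusp5 did not pass without M33-MEIS1 replicate 3 (adjusted p = 0.247) or MEIS1-deltaHD replicates 1 (adjusted p = 0.111), 2 (adjusted p = 0.053) and 3 (adjusted p = 0.159).

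Several lists passed in M33-MEIS1 against MEIS1-deltaHD with 0 or 1 member past the gene threshold in limma. They were stem and progenitor genes (0 higher, 1 lower, 1 and 6 adjusted over the list alone, median -0.0033, adjusted p = 5.16e-03, adjusted p = 0.273 with an estimated correlation), where Mycn was the gene, and chemokines (1 higher, 4 adjusted over the list alone, median 0.13, adjusted p = 2.34e-03, adjusted p = 0.381 with an estimated correlation), where Ccl6 was the gene. Interferon genes (1 higher, 3 adjusted over the list alone) had a median of 0.24 (adjusted p = 2.52e-03, adjusted p = 0.431 with an estimated correlation). Hypoxia genes (1 higher, 2 adjusted over the list alone) had a median of 0.11 (adjusted p = 1.17e-04, adjusted p = 0.367 with an estimated correlation). The p53 targets (1 higher, 3 adjusted over the list alone) had a median of 0.16 (adjusted p = 2.34e-03, adjusted p = 0.273 with an estimated correlation). The chemokine list did not pass without MEIS1-deltaHD replicate 2 (adjusted p = 0.0645), nor the interferon list without M33-MEIS1 replicate 3 (adjusted p = 0.0543). Of 9 erythroid genes 0 passed by limma, with 2 higher at an unadjusted p below 0.05 (median 0.20, adjusted p = 0.0317, adjusted p = 0.387 with an estimated correlation), and of 15 cholesterol genes 0 passed, with 3 higher at an unadjusted p below 0.05 (median 0.08, adjusted p = 0.0263, adjusted p = 0.467 with an estimated correlation). The erythroid list did not pass without M33-MEIS1 replicate 1 (adjusted p = 0.141) or 3 (adjusted p = 0.137), or without MEIS1-deltaHD replicate 1 (adjusted p = 0.109) or 2 (adjusted p = 0.111). The cholesterol list did not pass without M33-MEIS1 replicate 1 (adjusted p = 0.168) or 2 (adjusted p = 0.264), without MEIS1-deltaHD replicate 1 (adjusted p = 0.0733) or 2 (adjusted p = 0.205), or after median scaling (adjusted p = 0.156).

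In all, 142 genes passed between M33-MEIS1 and MEIS1-deltaHD, 134 higher and 8 lower, of which 31 differed by at least 1, and 2145 had an unadjusted p below 0.05. The count was 58 without MEIS1-deltaHD replicate 1, 65 without MEIS1-deltaHD replicate 2 and 61 without M33-MEIS1 replicate 3. It was 31 without an intensity trend, where Cma1 (adjusted p = 0.0631), F13a1 (adjusted p = 0.152), Ms4a6d (adjusted p = 0.0567) and Pf4 (adjusted p = 0.127) did not pass, 88 with no filter and 86 after median scaling.

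**Figure D4:**
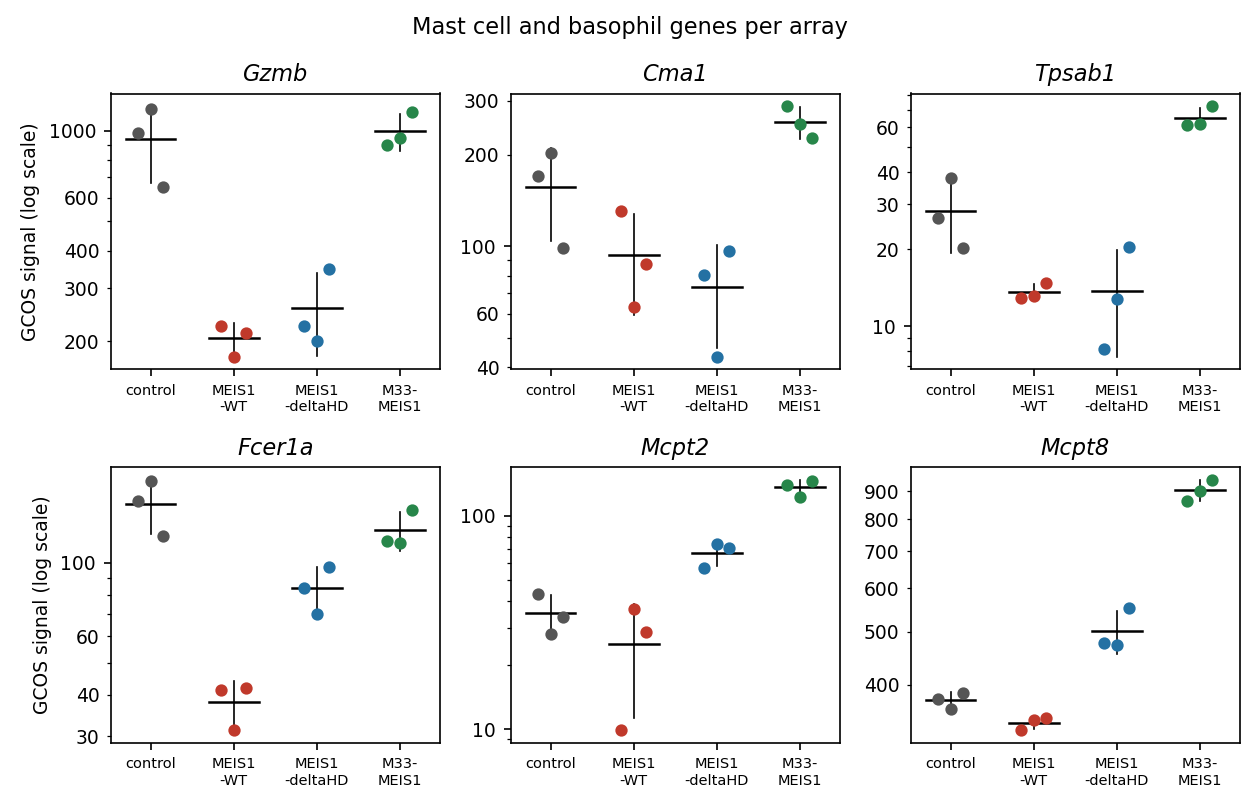
GCOS signal per array on a log axis for 6 mast cell and basophil genes, with 1 point per array, a line at the mean and bars of 1 SD (n = 3). Gzmb has means of 939 in control, 205 with MEIS1-WT, 258 with MEIS1-deltaHD and 999 with M33-MEIS1.

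Set directly against MEIS1-WT, M33-MEIS1 had higher monocyte, granulocyte and mast cell genes and lower genes linked to Meis1 and of the immediate early response. The comparison asks how joining M33 alters the effect of MEIS1. Csf1r was 634 ± 19.8 with M33-MEIS1 and 32.3 ± 5.86 with MEIS1-WT (log2 difference 3.76 ± 0.0914, adjusted p = 3e-19), and Lyz2 was 1345 ± 114 against 112 ± 13 (3.42 ± 0.0814, adjusted p = 3e-19). Dlk1 was 159 ± 13.5 against 1633 ± 183 (-3.23 ± 0.106, adjusted p = 1.21e-16). Hlf, a transcription factor of blood stem cells, was 71.9 ± 10.4 against 433 ± 20.3 (-2.36 ± 0.129, adjusted p = 2.64e-12).

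Other higher genes with M33-MEIS1 relative to MEIS1-WT were Tgfbi (3.53), Ifitm6 (3.34) and Lyz1 (3.42), and Lyz1 was at -0.018 with shared probe sets left out. With all kept probe sets tested singly, a further Lyz1 probe set passed in the same direction, at 4.27. Other lower genes were Ddx4 (-2.96), Slc35d3 (-2.68) and Rgs1 (-2.23). Flt3 fell to 84.4 from 331 (-1.80, adjusted p = 2.3e-10), Ccl3 to 1758 from 3431 (-0.96, adjusted p = 1.78e-06) and Trib2 to 10.9 from 61.6 (-1.52, adjusted p = 1.37e-05), where Trib2 was at -0.51 (adjusted p = 0.228) with shared probe sets left out. Monocyte genes were higher in 16 of 20 and lower in 0 (19 and 0 adjusted over the list alone, median 1.68, adjusted p = 6.42e-52). Mast cell genes were higher in 12 of 13 and lower in 0 by both counts (median 1.26, adjusted p = 2.91e-26), including Gzmb (2.20), Mcpt2 (1.95), Tpsab1 (1.45) and Fcer1a (1.38). Secondary granule genes were higher in 9 of 15 and lower in 0 by both counts (median 0.80, adjusted p = 1.48e-20), including Cybb (3.06), S100a9 (2.81) and S100a8 (2.37). Primary granule genes were higher in 10 of 14 and lower in 0 (13 and 0 adjusted over the list alone, median 0.53, adjusted p = 1.89e-16), including haptoglobin (Hp, 1.31) and Elane (1.30).

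The genes linked to Meis1 were lower with M33-MEIS1 than with MEIS1-WT in 11 of 14 and higher in 0 (0 and 12 adjusted over the list alone, median -0.93, adjusted p = 5.8e-23), with the same limit from the series title. Immediate early genes were lower in 10 of 21 and higher in 0 (0 and 15 adjusted over the list alone, median -0.47, adjusted p = 3e-13), including Egr1 (-1.72), Egr3 (-1.55), the feedback inhibitor Spry2 (-1.09) and Jun (-1.08). Stem and progenitor genes were lower in 8 of 20 and higher in 1 (2 higher and 10 lower adjusted over the list alone, median -0.20, adjusted p = 2.51e-07), with Mycn at -1.15 and Prom1 at 1.08. These 7 lists also passed with an estimated correlation. Interferon genes were higher in 3 of 17 and lower in 0 (8 and 0 adjusted over the list alone, median 0.28, adjusted p = 4.99e-04, adjusted p = 0.422 with an estimated correlation). Cholesterol genes were lower in 2 of 15 and higher in 0 (0 and 6 adjusted over the list alone, median -0.19, adjusted p = 3.73e-03, adjusted p = 0.422 with an estimated correlation), a call lost without M33-MEIS1 replicate 3 (adjusted p = 0.059) or MEIS1-WT replicate 3 (adjusted p = 0.0748). ATF4 targets were lower in 3 of 18 and higher in 1 (1 higher and 5 lower adjusted over the list alone, median -0.14, adjusted p = 0.0218, adjusted p = 0.304 with an estimated correlation), a call lost without M33-MEIS1 replicate 1 (adjusted p = 0.052) or MEIS1-WT replicates 2 (adjusted p = 0.0571) and 3 (adjusted p = 0.0671). G2/M genes had a median of 0.13 (adjusted p = 0.0404, adjusted p = 0.667 with an estimated correlation), with 1 of 19 higher over all genes and 0 adjusted over the list alone by limma. That call was lost without M33-MEIS1 replicate 1 (adjusted p = 0.171), MEIS1-WT replicate 1 (adjusted p = 0.0936) or 2 (adjusted p = 0.0881), and after median scaling (adjusted p = 0.0774). In all, 1292 genes passed, 821 higher and 471 lower, of which 260 differed by at least 1.

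**Figure D5:**
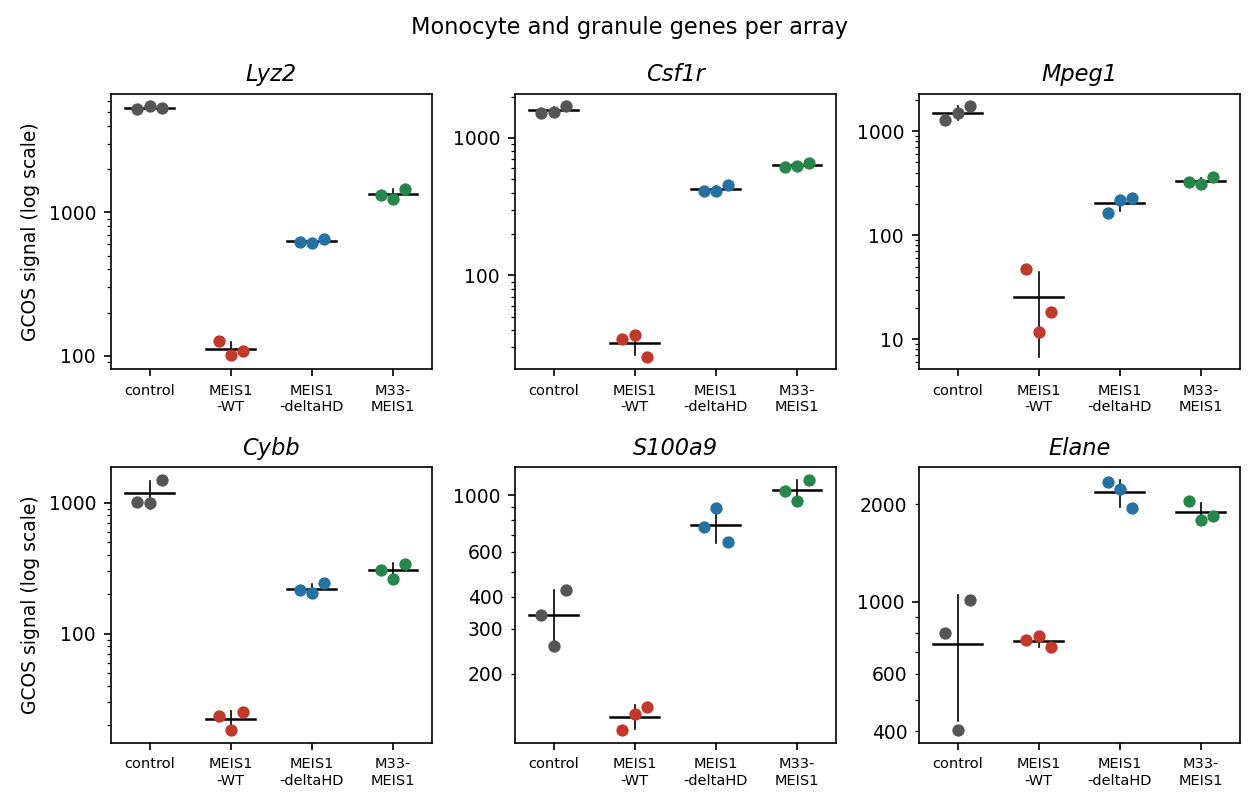
GCOS signal per array on a log axis for myeloid genes, with 1 point per array, a line at the mean and bars of 1 SD (n = 3). Csf1r has means of 1590 in control, 32.3 with MEIS1-WT, 425 with MEIS1-deltaHD and 634 with M33-MEIS1.

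The genes that moved in MEIS1-WT against both control and MEIS1-deltaHD numbered 591 in the same direction, and 385 without an intensity trend. Of the 591, 186 were higher, where 64.7 would be expected of independent lists, and 405 were lower, where 110 would be expected. The higher genes with the largest changes were Slc35d3, Dlk1, Ddx4, Rasgef1b (1.91 against control and 1.99 against MEIS1-deltaHD) and Spin4 (1.68 and 1.67). The lower ones were Csf1r, Ifitm6, Cybb, Igsf6 and Mpeg1. Both comparisons use the MEIS1-WT arrays, which alone gives a correlation of 0.50 between unchanged log2 differences in simulation, against an observed 0.351. Simulated unchanged groups shared at most 0.03 calls on average in the 5 pairs of comparisons that were simulated. That count was low by design, since hardly any gene passes where no group differs. It is no measure of the overlap that shared arrays give among real calls. The numbers expected of independent lists leave the shared arrays out and are no such measure either.

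MEIS1-WT and M33-MEIS1 moved 4520 genes in the same direction against control, 1997 higher (330 expected of independent lists) and 2523 lower (711 expected). The shared higher genes with the largest changes were Scd1, Tfrc, Tk1, Fen1 and Hsd17b7, and the lower ones Rtp4, Slfn4, Ifit1bl1, Usp18 and Rsad2. MEIS1-WT and MEIS1-deltaHD shared 2170 higher and 2973 lower genes, and MEIS1-deltaHD and M33-MEIS1 shared 2220 and 3012. All 3 constructs shared 1914 higher and 2353 lower genes. The log2 differences of MEIS1-WT and M33-MEIS1 correlated at 0.810 across genes, and their covariance exceeded the simulated one by 0.177. The 3 control arrays stand in each of these comparisons and are too few to be divided between them. A part of the overlap above the simulated and the independent level may therefore come from the shared controls.

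In opposite directions against control with MEIS1-WT and M33-MEIS1, 61 genes passed. Independent lists would give 489 and 480, but the shared control arrays push calls to the same direction, so these numbers are no measure for the 61. The count was 2 with a required log2 difference of 1. With all probe sets tested singly it was 163, but there the calls of a gene in the 2 comparisons may come from different probe sets. That number therefore cannot be set against the 61. The 31 that were higher with MEIS1-WT and lower with M33-MEIS1 included Hlf (1.10 and -1.26), Rgs1 (1.27 and -0.96) and Flt3 (1.00 and -0.80). The 30 that were lower with MEIS1-WT and higher with M33-MEIS1 included S100a9 (-1.21 and 1.60), S100a8 (-1.52 and 0.85) and Tfec, a transcription factor of macrophages (-1.08 and 0.82). All 61 also passed in the direct comparison of M33-MEIS1 with MEIS1-WT.

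Several lists passed in none of the 6 comparisons by camera. Of 18 measured Polycomb genes, 4, 7 and 4 were lower and 1, 2 and 1 higher than control with MEIS1-WT, MEIS1-deltaHD and M33-MEIS1 (4, 8 and 4 lower and the same numbers higher adjusted over the list alone), and the list medians were -0.13, -0.26 and -0.19 (adjusted p = 0.859, 0.246 and 0.359). Of 13 Hoxa cluster and partner genes, 3, 2 and 1 were higher and 3, 4 and 3 lower than control, with adjusted p = 0.97, 0.833 and 0.359. In the dendritic cell list of 11 genes, 5, 5 and 3 were lower and 1, 0 and 0 higher than control by both counts (adjusted p = 0.086, 0.0903 and 0.127), including the MHC class II chaperone Cd74 with MEIS1-WT (-2.75), a gene chosen after its values were seen. Of 11 D cyclins and cell cycle inhibitors, 4, 5 and 4 were lower and 1 higher each by both counts (adjusted p = 0.81, 0.341 and 0.359). Of 6 B cell genes, 1, 3 and 1 were lower and 0 higher by both counts (adjusted p = 0.599, 0.27 and 0.419). Of 7 T and NK cell genes, 1 was lower and 0 higher in each (adjusted p = 0.904, 0.676 and 0.995). Of 13 fibroblast genes, markers of the cell type that produced the virus, 2, 2 and 1 were lower and 0 higher than control by both counts (adjusted p = 0.696, 0.351 and 0.286). Each list that passed kept its direction relative to all other genes after quantile normalization and after median scaling. A shift common to all genes can hardly change that direction, so this says little about the list medians themselves.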

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

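The tests of explanations in this part were chosen after the result was seen, and the counts over other splits of the arrays were planned.

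In the control cultures, interferon and monocyte genes were high and cholesterol, G1/S and heat shock genes low relative to all 3 constructs, though the monocyte list did not pass for M33-MEIS1 with an estimated correlation (adjusted p = 0.0555). The authors' scaling of each array was tested with both other scalings, and the interferon list stayed at -2.96 or below in every construct. Rescaling moved the median of all genes against control by at most 0.255, so it could hardly have brought this list near 0. The interferon difference is thus larger than such a shift, and the other lists were not tested in this way. More monocytic cells in the control cultures could carry the interferon genes. M33-MEIS1 kept a median of 33.6% of the control excess over MEIS1-WT in 19 monocyte genes and 1.82% in 17 interferon genes. The difference was -31.8 percentage points (95% bootstrap interval -42.1 to -18.5, 10000 draws of the members, which are not independent replicates). A mere change in the share of uniform monocytic cells would leave both lists the same percentage, so these values argue against that alone. The test cannot exclude monocytic cells as the source, since their genes need not all fall by 1 common factor. Another growth state or handling of the control cultures stays open, since the G1/S list was at least 0.80 higher in each construct and every control array shares both the vector and its culture history, so the 2 cannot be told apart. An effect that all forms of MEIS1 share stays open as well, as untested.

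Monocyte genes were lower with MEIS1-WT than with either other construct. No single array accounts for this, because the median of the list was still -1.15 in the case nearest to 0, without MEIS1-deltaHD replicate 3. With the other scalings the median was -1.19 in the nearest case, after quantile normalization. Rescaling shifted the median of all genes by -0.0651 at most, in MEIS1-WT against MEIS1-deltaHD, and could hardly have removed the difference. A smaller share of monocytic cells in the MEIS1-WT cultures may account for the difference, or lower levels in the same cells. These cannot be told apart from bulk RNA of sorted cells, whose gate is not given here: the members differed from each other with an SD of 0.89, and no value tells which members other cells express.

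Mast cell genes were higher with M33-MEIS1 than with either other construct, and the effect against control was 1.26 larger with M33-MEIS1 than with MEIS1-WT (list median, from the direct test). The median of the list was still 0.80 without MEIS1-deltaHD replicate 1, the array whose absence lowered it most, which argues against a single array. It was also 0.80 after median scaling. Rescaling shifted the median of all genes by -0.0691 at most, in M33-MEIS1 against MEIS1-deltaHD, and could hardly have removed the difference. Against control, 9 of 13 genes of the list were lower and 1 higher with MEIS1-WT (median -0.65), a list that passed at the preset correlation only. With MEIS1-deltaHD 9 were lower and 3 higher (median -0.73), and the list did not pass (adjusted p = 0.0903). The cultures held IL-3 and stem cell factor, in which mast cells grow. A larger share of mast cells or basophils with M33-MEIS1, or a smaller one with the other constructs, may be the source. Other levels in the same cells may be the source as well. With an SD of 0.49 between the members' log2 changes and no count of cells, these cannot be told apart.

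Some genes went opposite ways against control in different constructs: 61 between MEIS1-WT and M33-MEIS1 and 54 between MEIS1-WT and MEIS1-deltaHD, all past the direct test between the constructs. The Meis1-linked list differed by -0.93 between M33-MEIS1 and MEIS1-WT (list median, from the direct test). A Cbx2 probe set not used in the comparisons read 51.3 with M33-MEIS1, above the 7.12 of control. The array-control probe set for the 3' end of the transferrin receptor, also outside the comparisons, was above every control array on 9 of 9 construct arrays, at 549 ± 45.4, 654 ± 40 and 539 ± 74.2 with MEIS1-WT, MEIS1-deltaHD and M33-MEIS1 and 118 ± 39.6 in control.

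Each comparison of 3 arrays with 3 has 10 splits, too few for a share below 0.05. The real split alone (1 of 10) gave as many genes in each comparison, and the highest count in the others was 1 gene for M33-MEIS1 against MEIS1-deltaHD and 0 in the other comparisons by limma. For the lists at the preset correlation the real counts were 13, 12 and 13 against control (MEIS1-WT, MEIS1-deltaHD, M33-MEIS1), 14 for MEIS1-WT against MEIS1-deltaHD, 12 for M33-MEIS1 against MEIS1-deltaHD and 11 for M33-MEIS1 against MEIS1-WT. The highest counts of the other splits were 11, 15, 12, 11, 11 and 12 in that order, and 1, 3, 1, 1, 1 and 2 of the 10 splits, the real one included, gave as many lists. Some mixed splits thus gave nearly as many lists as the real one, or more. The number of lists that pass at the preset correlation hardly sets the real groups apart, and a pass at that correlation alone is weak evidence. With an estimated correlation the real counts were 8, 6, 5, 4, 3 and 7, and the highest of the other splits was 0 by camera. The other splits mix groups that differ, which adds the difference to the residual spread and to the estimated correlation. Low counts of genes, and of lists with an estimated correlation, were therefore likely in advance in those splits. They cannot decide whether chance accounts for the real counts. For the overlaps, 100 splits of 9 arrays were drawn. A count of 591 genes moved in MEIS1-WT against both control and MEIS1-deltaHD was reached by 3 of 100 splits, the real one included. The highest other count was 5143, from a split that puts the control arrays in the place of MEIS1-WT, which points to the structure of the samples. The 4520 genes shared with M33-MEIS1 against control were reached by 1 of 100 splits, with 4143 as the highest other, and the 61 opposite genes by 1 of 100, with 0 as the highest other. Mixing the groups raised the median residual SD from 0.197 to as much as 0.280 in the first set of splits and to between 0.213 and 0.271 in the second, where only 3 of the other splits called genes in both comparisons with control. Low counts were therefore likely in advance, and these splits cannot decide whether chance is excluded for the 3 overlaps.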

How the results depend on the processing

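The list tests under median scaling and the count of further probe sets were chosen after seeing the data, and the other alternatives were planned. Leaving out 1 array in turn gave 5496 to 6759, 6196 to 7537 and 5228 to 6115 genes against control for MEIS1-WT, MEIS1-deltaHD and M33-MEIS1. It gave 692 (without MEIS1-deltaHD replicate 1) to 1205 genes for MEIS1-WT against MEIS1-deltaHD and 944 to 1481 for M33-MEIS1 against MEIS1-WT. For M33-MEIS1 against MEIS1-deltaHD it gave 58 (without MEIS1-deltaHD replicate 1) to 198, with 65 without MEIS1-deltaHD replicate 2 and 61 without M33-MEIS1 replicate 3. The overlaps ranged over 446 to 637, 3872 to 4427 and, for opposite directions, 46 to 62, and the list counts over 9 to 14. M33-MEIS1 against MEIS1-deltaHD gave 88 genes with no filter, 86 after median scaling and 31 without an intensity trend. Without the trend, MEIS1-WT against MEIS1-deltaHD gave 605 genes and MEIS1-WT against both gave 385. With all probe sets tested singly, 163 genes went opposite ways, but the calls of a gene may then come from different probe sets. That number is not comparable with the count from 1 probe set per gene. The cause of the other changes in these counts was not tested. A required log2 difference of 1, by construction stricter, gave 931, 928 and 634 genes against control, 169 for MEIS1-WT against MEIS1-deltaHD, 31 for M33-MEIS1 against MEIS1-deltaHD, 260 for M33-MEIS1 against MEIS1-WT, and overlaps of 107, 482 and 2. An estimated correlation gave 8, 6 and 5 lists against control, then 4, 3 and 7 in the order of the comparisons just given. Of 362 named-gene results, 7 changed sign. Cbx2, which had not passed, was at 1.56 (M33-MEIS1 against control) and 1.37 (against MEIS1-WT) with all probe sets tested singly. With shared probe sets left out, Tpsb2 was at -0.039 (M33-MEIS1 against MEIS1-deltaHD) and Lyz1 at -0.018 (M33-MEIS1 against MEIS1-WT). Pfkl was then at -0.30 (MEIS1-WT against control) and Plagl1 at -0.16 and 0.23 (MEIS1-WT and M33-MEIS1 against control). In all 7, another probe set of the gene was used, and the cause was not tested further. With all kept probe sets tested singly, no further probe set of Tpsb2, Lyz1, Pfkl or Plagl1 passed in the opposite direction in these comparisons. Of 155 named-gene results that passed and had further kept probe sets, 112 had at least 1 more with the same call, 43 had none, and 3 had 1 with the opposite call. Mycn and Jun (M33-MEIS1 against MEIS1-deltaHD), Ddit3 and Tubb6 (MEIS1-deltaHD against control), Itgb3 (MEIS1-WT against MEIS1-deltaHD) and Spry2 (M33-MEIS1 against MEIS1-WT) are among those with none. The other alternatives kept direction and side of the threshold in 4173 named-gene cases and lost 110, and leaving out 1 array kept 4228 and lost 111. For the lists that passed, with the direction taken relative to all other genes, 405 cases kept both and 45 lost the call. With 1 array left out 876 kept both and 24 lost the call. Calls fell more often on the higher side after rescaling: 51.1%, 49.7% and 50.7% against control with quantile normalization and 67.5%, 70.8% and 70.0% with median scaling, in place of 40.7%, 37.8% and 40.3%. No shared effect of the replicate number was visible, since residuals of arrays with the same number correlated at -0.0385 to 0.0253. A replicate block gave 6409, 7196, 6041, 986, 143 and 1211 genes. These values cannot show whether arrays with the same number came from the same experiment. Signals near the background limit what dim genes can show, and the added 16 makes their log2 differences smaller.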

Other observations

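The genes and lists in this part were chosen after their values were seen, and the test of a hypothesis at its end was chosen after the result was seen. Among erythroid genes, the transferrin receptor rose against control while Tal1, a transcription factor of blood stem and erythroid cells, fell. Tal1 went from 401 ± 22.8 to 260 ± 27.7 with MEIS1-WT (log2 difference -0.60 ± 0.0879, adjusted p = 7.56e-06). It read 253 ± 6.98 with MEIS1-deltaHD (-0.63 ± 0.0879, adjusted p = 3.45e-06) and 296 ± 3.42 with M33-MEIS1. Of 9 erythroid genes 2 were higher and 2 lower with MEIS1-WT, and 5 did not pass. With MEIS1-deltaHD 1 was higher and 3 lower, and 5 did not pass. The list passed with neither (adjusted p = 0.97 and 0.993). Of 16 p53 targets 5 were higher and 5 lower with MEIS1-WT, 2 and 6 with MEIS1-deltaHD, and 4 and 5 with M33-MEIS1, and the list did not pass (adjusted p = 0.904, 0.51 and 0.721).

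Within lists that did not pass, single genes differed strongly from control in all 3 constructs. The interleukin 7 receptor Il7r was 73.4 ± 22.2 in control and 9.17 ± 5.18, 12.8 ± 5.67 and 19.9 ± 7.49 with MEIS1-WT, MEIS1-deltaHD and M33-MEIS1 (adjusted p = 4.66e-07, 2.58e-06 and 6.01e-05). The Polycomb genes Ezh1 and Phc2 were lower as well, with Ezh1 at 145 ± 9.43 in control and 71.4 ± 2.41, 71.1 ± 5.29 and 86.9 ± 5.27 with the constructs, and Phc2 at 393 ± 13.9 and 245 ± 18.6, 253 ± 16.6 and 224 ± 36.1. The MHC class II chaperone Cd74 was 272 ± 33.4 in control and 27.3 ± 8.12, 56.1 ± 13.1 and 90.3 ± 30.4 with the constructs.

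A hypothesis was that M33-MEIS1 lowers the genes that MEIS1-WT raises over MEIS1-deltaHD, since by its name it joins MEIS1 to a protein of repressive chromatin. It was tested on the 485 genes raised by MEIS1-WT, where M33-MEIS1 would then lie below MEIS1-deltaHD. The median log2 difference of M33-MEIS1 from MEIS1-deltaHD was 0.13, above the 0.0570 to 0.0768 of 50 simulations with no effect of M33-MEIS1, in which the shared MEIS1-deltaHD arrays alone raise it. Of the 485 genes, 25 passed as higher and 1 as lower than with MEIS1-deltaHD, while 271 passed as lower than with MEIS1-WT. The hypothesis was not borne out for the set. For the 565 genes lowered by MEIS1-WT the median difference of M33-MEIS1 from MEIS1-deltaHD was 0.07, above the -0.0589 to -0.0388 of the same simulations, and 48 passed as higher and 4 as lower. The simulations hold no shift of whole arrays. The median of all genes between M33-MEIS1 and MEIS1-deltaHD was 0.0249, and -0.0442 after median scaling. A part of the excess over the simulations may therefore come from the scaling of the arrays, which was not tested here.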
